A study of Mus musculus with 9 samples.

How the data were processed

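RNA-seq libraries of αTC1 cells were analysed, 5 after 7 days with DMSO and 4 after 7 days with 4 µM EPZ011989, grouped by the treatment in the labels. Per the labels' protocols, poly-A RNA was captured from total RNA and made into Illumina libraries. The submitters' processing notes name HISAT2, StringTie, DESeq2 and the mouse build mm10, without roles or versions, and strand use in counting was not given in the sources used here. The authors deposited a table of whole-number gene counts with 33212 rows, and a second, normalized table of 20796 rows on a linear signal scale. In every library, 100% of the matched values of the normalized table were the deposited count divided by 1 factor. The most frequent count above 0 was 1 (3970 values), but counts of 4 (3046) and 5 (2732) were more frequent than 2 (2108) or 3 (2160), and counts rose in number again at 8 and 9. Many fragments thus appear to add about 4 counts and others fewer, and counts are not independent reads. Some symbols of the normalized table had been turned into dates, and 20590 of its rows matched the count table by symbol. The count table was therefore used, and symbols shared by several rows (136) were kept apart by gene identifier.

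Genes were filtered with filterByExpr, scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, all 9 libraries, treatment as the only term) in R 4.3.3. P-values are two-sided and adjusted by the Benjamini-Hochberg method over 14754 genes, with calls at an adjusted p under 0.05. CPM values use TMM-scaled library sizes, means are given ± SD between libraries, and log2 fold changes with approximate standard errors (SE). Each such SE is the size of the log2 fold change divided by the square root of its F statistic. Lists of genes fixed before the data were examined (42, on Polycomb, islet identity, metabolism, signalling, stress and other cell types) were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. Camera was repeated with the correlation estimated per list, and fry was used as an alternative. At the preset correlation, camera called up to 8 lists in splits with 2 EPZ011989 libraries on each side. Its adjusted p-values can thus be too small. Counts adjusted over the list alone use Benjamini-Hochberg adjustment within a list. All counts of list members cover only those that passed the filter. Gene positions and overlapping exons come from GENCODE M21 on GRCm38, the same assembly as mm10.

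Named genes followed a rule set before the data were examined. It took the 15 largest rises and 15 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, 20 genes of alpha, beta and other islet cells and EZH2 biology whether called or not, and up to 4 called members of each list by smallest p. Unnamed gene models were not named, and members of the first and last part could be left out. Some genes that the rule takes are not reported here. Exons of 46 of these 177 genes overlap those of another gene.

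Library depth was 60274140 to 74651782 deposited counts. For a gene at 0 the floor was 12 counts per library (3 fragments at about 4 counts each), and folds against a group at 0 are lower bounds at that floor. Floors cover counting error only, since libraries had no molecular identifiers in the sources used here. Counts were simulated with the DMSO means and the real library sizes and dispersions for 14754 genes. The fit recovered 89% of 100 genes changed 2-fold and 100% of 100 changed 4-fold, with 8 false calls. Changed genes had a DMSO mean of at least 1 CPM, so recovery below that was not tested. Of the 1282 real rises of at least 2-fold, 561 had a mean under 1 CPM. The simulation held neither steps of about 4 counts nor length trends between libraries. No pair of replicates agreed within sampling noise (lowest chi-square per degree of freedom 4.19 after dividing counts by 4), so no library was counted as a duplicate.

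Alternatives planned before the data were examined were RLE and upper-quartile factors, library size alone, no filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, limma on log2(value + 1) and log2(value + 10) of the normalized table, glmTreat against a fold of 1.5, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were counts divided by 4, removal of a trend with transcript length, and leaving out EPZ011989 libraries 2 and 4, which lay at opposite ends of the second principal component.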

Results

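Poly-A RNA was sequenced from αTC1 cells, a glucagon-producing cell line derived from mouse pancreatic alpha cells, after 7 days with 4 µM EPZ011989 (n = 4) or with the solvent DMSO (n = 5). EPZ011989 inhibits EZH2, the catalytic subunit of the Polycomb repressive complex PRC2, which methylates lysine 27 of histone H3 at silent genes. The labels call the libraries biological replicates. They do not say whether these were separate cultures, so p-values measure the spread between these libraries. Total counts per library lay between 60274140 and 74651782, and the first principal component, with 58.0% of the variance, separated the groups. Libraries of the same group correlated at r = 0.966 to 0.986 across genes, and libraries of different groups at r = 0.945 to 0.959. The series has a single comparison, EPZ011989 against DMSO, which asks how inhibition of EZH2 alters gene expression in αTC1 cells. The title places it in a study of beta cell formation from alpha cells with altered metabolism.

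EPZ011989 mainly raised genes that were low or undetected in DMSO cells. Among members passing the filter, 12 of 24 Hox genes, 27 of 50 developmental transcription factors and 14 of 24 Wnt pathway genes rose. So did 14 of 18 antigen presentation genes and 8 of 11 fibroblast markers. In that order, the full lists held 39, 137, 41, 21 and 18 genes. A gene at 0 in DMSO passes the filter only through the EPZ011989 libraries, which can raise these shares. Of 23 genes of serine, glycine and one-carbon metabolism 13 fell and 1 rose. Gcg, which encodes glucagon, was the most abundant islet hormone transcript in both groups, at 19280 ± 804 CPM (SD, n = 5) in DMSO and 18633 ± 2338 CPM (n = 4) with EPZ011989, a difference within the spread between libraries (adjusted p = 0.778, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Ins2 and Sst, which encode insulin and somatostatin, rose from near or below detection to a few CPM or less.

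Of 14754 genes tested, 2388 were higher and 1174 lower at an adjusted p under 0.05 in the edgeR quasi-likelihood test. At least 2-fold changes were far more one-sided, with 1282 genes higher and 43 lower. The groups did not overlap for 2376 genes that were higher and 1294 that were lower with EPZ011989, where chance gives 0.794% of genes in each direction. Among genes with a mean under 1 CPM, 563 rose and 15 fell, while among those at 100 CPM or more 110 rose and 362 fell. Camera compares a list with all tested genes, unmatched on level, so list calls can carry this trend. With upper-quartile factors in place of TMM factors, 2735 genes were higher and 776 lower, so higher genes made up 77.9% of the calls in place of 67.0%. The count of lower genes depended on single libraries. It was 2377 without EPZ011989 replicate 2 and 781 without replicate 3, and the count lower by at least 2-fold was 103 without replicate 2. Without replicate 2, 5316 genes were called in place of 3562, so many genes pass there that do not pass with all 9 libraries.

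**Figure D1:**
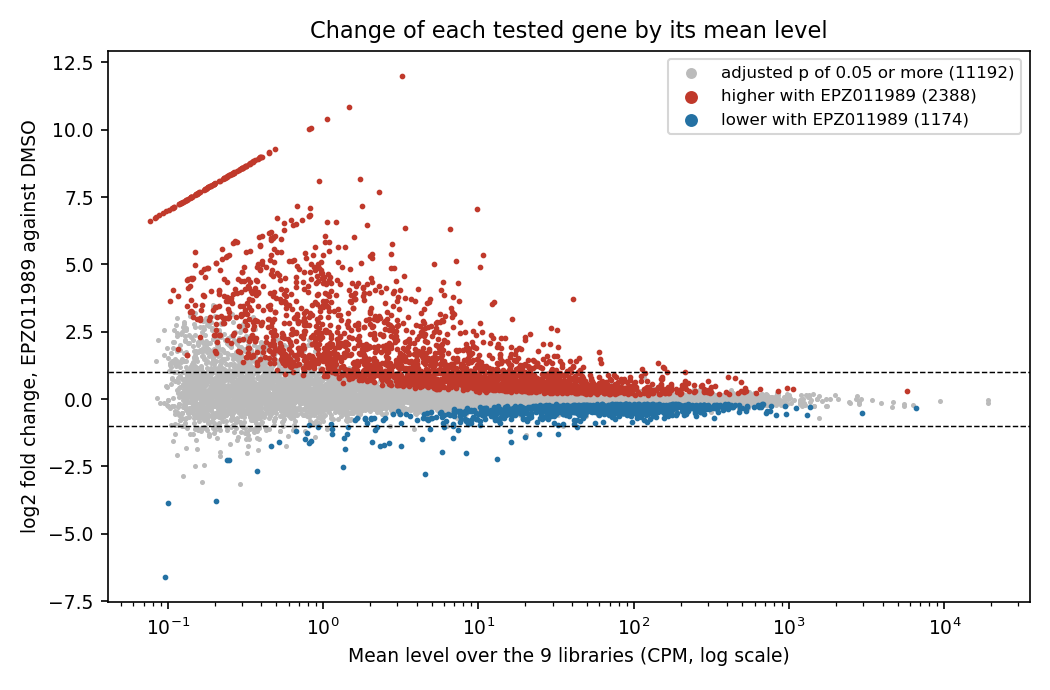
Each point is 1 of the 14754 tested genes, with its mean level over the 9 libraries in CPM on a log axis against its log2 fold change, EPZ011989 against DMSO. The 2388 higher genes (red) reach large changes at low levels, the 1174 lower genes (blue) lie mostly between the dashed line at a 2-fold fall and no change, and points along the upper diagonal are genes without a count in DMSO, whose fitted values are not bounds.

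Ezh2 itself (chromosome 6, 47530139 to 47595341, GRCm38) was at 199 ± 5 CPM in DMSO and 209 ± 7 CPM with EPZ011989, a log2 fold change of 0.07 ± 0.05 (SE) that did not pass the edgeR test (adjusted p = 0.407). Its paralog Ezh1 was at 36.6 ± 2.3 and 38.5 ± 2.0 CPM (adjusted p = 0.548). Among 11 measured PRC2 subunits, Jarid2 rose (33.6 to 42.6 CPM), Rbbp7 fell (388 to 326 CPM) and 9 did not pass. Adjusted over the list alone, the counts were again 1 and 1, and the list as a whole was not called (camera adjusted p = 0.386).

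The 15 largest rises among genes with a mean of at least 5 CPM ran from 135-fold to 11.4-fold. Pcp4, a calmodulin-binding protein of neurons, rose from 0.160 ± 0.0995 to 21.9 ± 3.6 CPM (log2 fold change 7.08 ± 0.30 SE, adjusted p = 2.64e-07, edgeR). Its exons overlap those of Igsf5, and strand use in the counting was not stated. Pak1, a serine/threonine kinase, rose from 0.177 ± 0.182 to 14.6 ± 2.7 CPM, and Rtn1, a reticulon of neurons and endocrine cells, from 0.585 ± 0.244 to 23.5 ± 1.8 CPM. Bmp7, a secreted BMP ligand, rose 35.3-fold to 15.7 ± 0.9 CPM. Collagen VI chain Col6a2 rose 32.4-fold, and Lgr5, an R-spondin receptor that is itself a Wnt target, from 0.781 ± 0.295 to 15.7 ± 3.3 CPM. The most abundant of these 15 was Igfbp5, an insulin-like growth factor binding protein, at 6.41 ± 0.61 CPM in DMSO and 83.7 ± 3.8 CPM with EPZ011989 (log2 fold change 3.71 ± 0.09 SE, adjusted p = 3.22e-09, edgeR). Prkar2b (14.4-fold), a regulatory subunit of protein kinase A, St3gal1 (12.2-fold), a sialyltransferase, and the receptor tyrosine kinase gene Ephb2 (11.4-fold) were also among them.

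Falls were smaller. Tmem27 (collectrin) fell most among genes of this level, from 20.2 ± 1.1 to 4.33 ± 0.36 CPM (log2 fold change -2.22 ± 0.09 SE, adjusted p = 2.64e-07, edgeR). Gpr119, a lipid-sensing receptor of islet and enteroendocrine cells, fell from 12.5 ± 2.2 to 3.13 ± 1.26 CPM. Kcnk16, which encodes the islet potassium channel TALK-1, fell from 9.46 ± 0.66 to 3.49 ± 0.36 CPM. Rfx6, a transcription factor needed for islet cell formation, fell from 44.2 ± 1.8 to 18.04 ± 5.86 CPM, and Klb, the co-receptor for FGF21, from 21.4 ± 1.4 to 9.28 ± 1.17 CPM. Others of the 15 were Folh1, Upb1, Sgk2 and Napb, at 0.255, 0.381, 0.403 and 0.482 times their DMSO levels.

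Alpha cell identity genes did not fall past the threshold. Of 17 measured, 4 rose and 0 fell, the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.906). Wnt4, a secreted signalling protein, rose from 170 ± 8 to 272 ± 58 CPM (log2 fold change 0.68 ± 0.13 SE, adjusted p = 0.00277, edgeR), and Peg10, an imprinted gene, from 81.1 ± 11.9 to 126 ± 31 CPM. Irx1, at 185 ± 14 and 208 ± 32 CPM, and Irx2, at 181 ± 9 and 172 ± 6 CPM, did not pass. Without EPZ011989 replicate 2, Irx1 passed (log2 fold change 0.26, adjusted p = 0.0152), in a fit that called 5316 genes in place of 3562.

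Among 18 measured beta cell identity genes 10 rose and 2 fell, also when adjusted over the list alone. As a list they did not pass (camera adjusted p = 0.0579, and adjusted p = 0.180 with an estimated correlation). The list passed when DMSO replicate 1, 3, 4 or 5 or EPZ011989 replicate 1 or 4 was left out, with adjusted p of 0.0455, 0.0269, 0.0180, 0.0417, 0.0278 and 0.0344. Ins2 (chromosome 7, 142678656 to 142743381) rose 7.41-fold, from 0.653 ± 0.243 to 4.85 ± 1.46 CPM (log2 fold change 2.89 ± 0.30 SE, adjusted p = 5.72e-05, edgeR), with every EPZ011989 library above every DMSO library. Mafa, a transcription factor of mature beta cells, rose from 0.541 ± 0.282 to 1.78 ± 0.30 CPM, and Npy, a neuropeptide of immature beta cells, from 0.0797 ± 0.0886 to 1.96 ± 0.47 CPM. Slc30a8, the zinc transporter of insulin and glucagon granules, fell from 298 ± 13 to 192 ± 42 CPM. Ins1 and Pdx1 had a count of 0 in all 9 libraries, which allows at most 0.158 to 0.203 CPM per library at 3 fragments of about 4 counts each. Nkx6-1, at 39.9 ± 2.4 and 44.3 ± 4.2 CPM, did not pass, but did without EPZ011989 replicate 2 (log2 fold change 0.21, adjusted p = 0.0315).

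Endocrine progenitor and pan-endocrine transcription factors, tested as 1 list, moved both ways. Of 19 measured, 3 rose and 4 fell, or 4 and 4 adjusted over the list alone, and the list was not called (camera adjusted p = 0.558). Sox9, a factor of ducts and pancreatic progenitors, rose from 10.8 ± 0.9 to 22.2 ± 1.4 CPM, and Isl1 from 475 ± 7 to 588 ± 24 CPM. Pax6 was at 104 ± 8 and 89.95 ± 8.89 CPM (adjusted p = 0.0869), and passed as lower without DMSO replicate 5 (0.0439) or EPZ011989 replicate 2 (0.0113). Neurod1, at 155 ± 8 and 152 ± 19 CPM, did not pass. Neurog3 and Pax4 each had a count in only 1 of the 9 libraries.

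Sst had a count of 0 in all 5 DMSO libraries and 0.866 ± 0.314 CPM in the 4 EPZ011989 libraries, at least 4.93-fold higher against a floor of 12 counts per DMSO library (adjusted p = 4.02e-04, edgeR). Ppy had counts in 2 EPZ011989 libraries only, and Ghrl, at 0.194 ± 0.078 and 0.353 ± 0.259 CPM, did not pass. Delta, PP and epsilon markers as a list were not called (3 of 8 rose, 0 fell, 3 and 0 adjusted over the list alone, camera adjusted p = 0.0739). Enteroendocrine hormone genes were called (3 of 6 rose, 4 adjusted over the list alone, camera adjusted p = 0.0308). That call was lost with adjusted p = 0.206 with an estimated correlation, with the filter of at least 1 CPM in 4 libraries (0.213), with the length trend removed (0.0539), without EPZ011989 replicate 2 (0.104) and without replicates 2 and 4 (0.0840). Nts rose from 0.0796 ± 0.0882 to 2.13 ± 0.69 CPM and Cck from 0.0383 ± 0.0857 to 1.38 ± 0.09 CPM. Vip, at 0 in every DMSO library, was at least 3.83-fold higher.

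**Figure D2:**
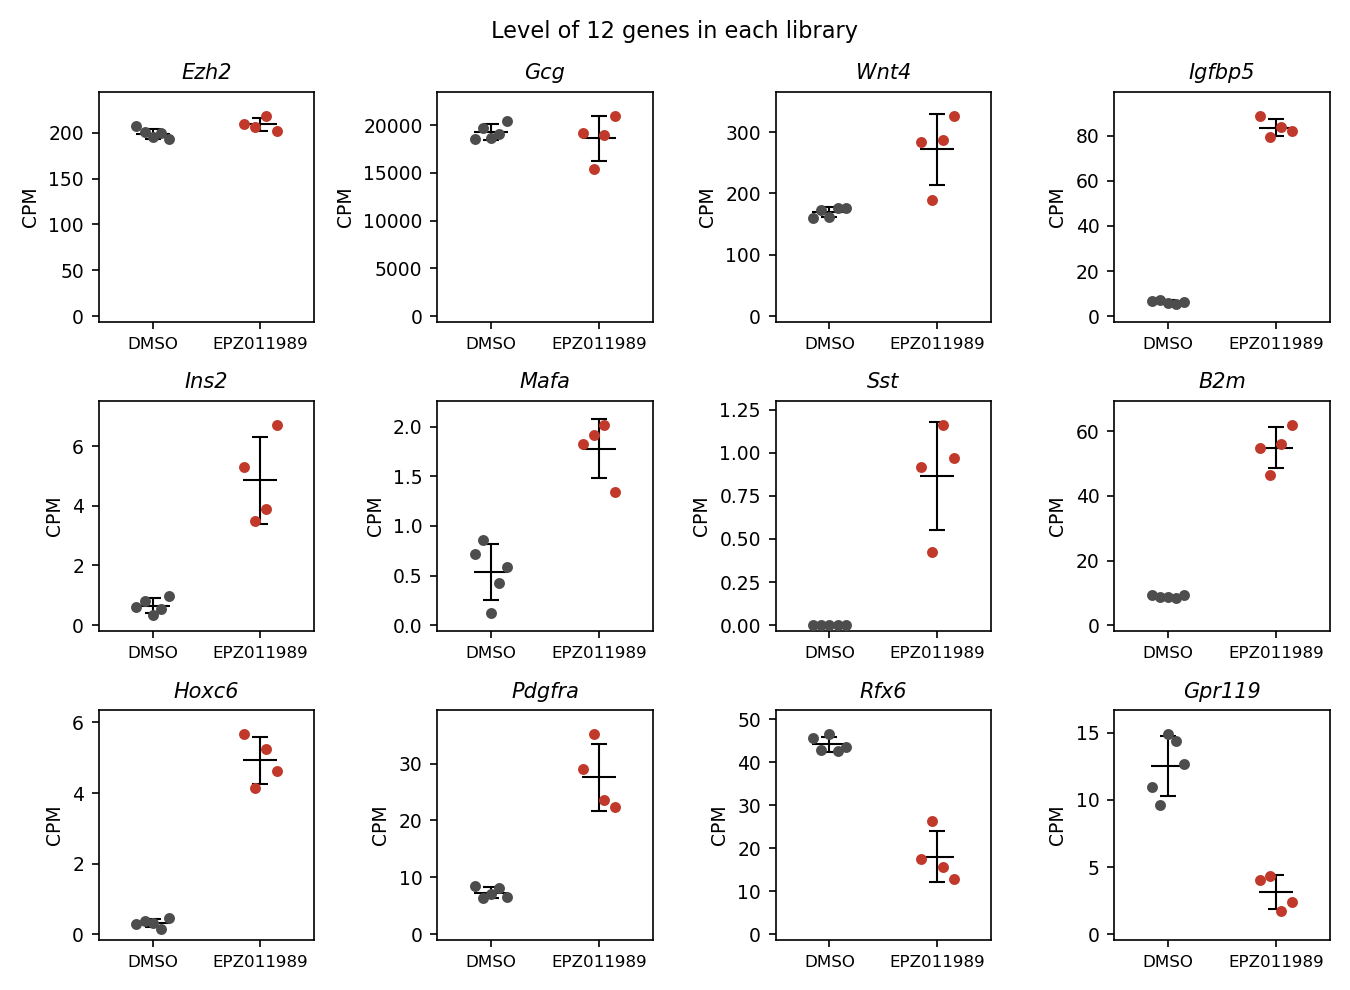
Levels in CPM of 12 genes in each library on linear axes that include 0, with DMSO in grey (5 points) and EPZ011989 in red (4 points), black bars giving the mean and SD. Ezh2 and Gcg overlap between groups, Wnt4, Igfbp5, Ins2, Mafa, Sst, B2m, Hoxc6 and Pdgfra lie above every DMSO library, and Rfx6 and Gpr119 lie below.

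Hox genes, which set position along the body axis and are classic Polycomb targets, rose for 12 of 24 measured members and fell for 0 (13 and 0 adjusted over the list alone, camera adjusted p = 2.93e-07, adjusted p = 0.0132 with an estimated correlation). By cluster, 1 of 9 measured genes rose in HoxA, 3 of 7 in HoxB, 7 of 7 in HoxC and 1 of 1 in HoxD, counts that were the same under TMM, RLE and upper-quartile factors and library size alone. Hoxc6 rose from 0.313 ± 0.113 to 4.93 ± 0.67 CPM, Hoxc9 from 0.113 ± 0.065 to 3.79 ± 0.91 CPM and Hoxc10, whose exons overlap those of Hoxc5, from 0.601 ± 0.186 to 6.18 ± 1.05 CPM. Hoxb13 rose from 8.14 ± 1.47 to 29.1 ± 5.5 CPM. Developmental transcription factors known as Polycomb targets rose for 27 of 50 measured members and fell for 2 (30 and 3 adjusted over the list alone, camera adjusted p = 1.26e-05, adjusted p = 0.0430 with an estimated correlation). The full list held 137 genes, and those below the filter were not tested. Lhx4, a LIM homeobox factor, rose from 0.612 ± 0.234 to 3.91 ± 0.24 CPM, and Lhx5, at 0 in every DMSO library, was at least 6.23-fold higher. Nr2f1, already at 33.7 ± 2.2 CPM in DMSO, fell to 21.2 ± 1.4 CPM.

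Antigen presentation genes rose for 14 of 18 measured members and fell for 1, also when adjusted over the list alone (camera adjusted p = 7.67e-12, adjusted p = 0.0144 with an estimated correlation). B2m, the light chain of MHC class I, rose from 8.83 ± 0.35 to 54.9 ± 6.4 CPM (log2 fold change 2.64 ± 0.09 SE, adjusted p = 8.52e-08, edgeR). Psmb9, an immunoproteasome subunit whose exons overlap those of Tap1, rose from 1.56 ± 0.35 to 8.30 ± 1.42 CPM. H2-D1 rose from 97.54 ± 6.14 to 225 ± 33 CPM and H2-Q4 from 16.3 ± 0.9 to 41.2 ± 3.5 CPM, but class I heavy chain genes are near-identical copies that can share reads, so the level of each is uncertain. The interferon response list, at 8 of 22 higher and 1 lower (10 and 1 adjusted over the list alone), was not called (camera adjusted p = 0.158), but passed with no filter (0.0294).

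Wnt pathway genes rose for 14 of 24 members and fell for 0 (16 and 0 adjusted over the list alone, camera adjusted p = 6.25e-07, adjusted p = 0.0278 with an estimated correlation). Besides Lgr5 and Wnt4, the receptor gene Fzd2 rose from 0.876 ± 0.292 to 6.26 ± 0.65 CPM, and the Wnt antagonist gene Wif1 from 0.365 ± 0.189 to 5.99 ± 1.34 CPM. Notch pathway genes rose for 7 of 14 and fell for 0 (8 and 0 adjusted over the list alone, camera adjusted p = 0.00396, adjusted p = 0.0618 with an estimated correlation). They included Notch2 (2.53 ± 0.31 to 6.66 ± 1.21 CPM), the ligand gene Dll1 (1.58 ± 0.62 to 6.67 ± 0.59 CPM) and Mfng, a glycosyltransferase that modifies Notch. In the TGF-beta and BMP pathway 10 of 24 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 4.82e-04, adjusted p = 0.201 with an estimated correlation), among them Gdf11 (4.04 ± 0.75 to 15.8 ± 1.1 CPM) and Tgfb2 (1.47 ± 0.32 to 6.25 ± 0.48 CPM). Neuronal genes rose for 10 of 27 and fell for 3 (13 and 6 adjusted over the list alone, camera adjusted p = 0.00276, adjusted p = 0.0618 with an estimated correlation), among them Gap43 (8.19 ± 1.23 to 30.9 ± 3.2 CPM) and Stmn2 (0.0225 ± 0.0308 to 5.12 ± 1.16 CPM). Of all tested genes under 1 CPM 20.8% rose, and of those at 1 to 10 CPM 33.4%. These pathway lists were not matched on level.

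Markers of other cell types were set beside low genes in general. Of all tested genes with a mean under 1 CPM 20.8% rose, and of those at 1 to 10 CPM 33.4%. Fibroblast and stellate cell markers rose for 8 of 11 members and fell for 0 (10 and 0 adjusted over the list alone, camera adjusted p = 1.29e-10, adjusted p = 0.00734 with an estimated correlation). Pdgfra, a growth factor receptor, rose from 7.29 ± 0.96 to 27.6 ± 5.9 CPM, Col6a1 from 0.463 ± 0.112 to 2.32 ± 0.40 CPM, and Thy1, at 0 in every DMSO library, was at least 18.6-fold higher at 3.28 ± 0.74 CPM. Endothelial markers (3 of 6 higher, 0 lower, 3 and 0 adjusted over the list alone, camera adjusted p = 0.276), macrophage and leukocyte markers (1 of 6 higher, 0 lower, 2 and 0 adjusted over the list alone, adjusted p = 0.301) and ductal markers (3 of 9 higher, 0 lower, also adjusted over the list alone, adjusted p = 0.131) were not called.

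Of 33 genes of the tricarboxylic acid cycle and pyruvate metabolism 15 fell and 1 rose (16 and 1 adjusted over the list alone, camera adjusted p = 2.57e-05), a call lost with an estimated correlation (adjusted p = 0.206 with an estimated correlation). Dlat, a subunit of pyruvate dehydrogenase, fell from 72.8 ± 3.1 to 55.3 ± 2.7 CPM (log2 fold change -0.40 ± 0.06 SE, adjusted p = 0.00103, edgeR), and the isocitrate dehydrogenase subunit gene Idh3a from 260 ± 3 to 207 ± 9 CPM. In serine, glycine and one-carbon metabolism 13 of 23 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 3.19e-04, adjusted p = 0.0413 with an estimated correlation). Aldh1l2, the mitochondrial folate enzyme, fell from 153 ± 11 to 84.3 ± 16.8 CPM, Psat1 of serine synthesis from 398 ± 20 to 284 ± 33 CPM and Cth of cysteine synthesis from 10.8 ± 1.3 to 5.75 ± 0.98 CPM. The exception was the cytosolic paralog Aldh1l1, which rose from 0.851 ± 0.278 to 2.78 ± 0.83 CPM. Amino acid transporters and targets of the stress factor ATF4 fell for 7 of 25 and rose for 1 (9 and 1 adjusted over the list alone, camera adjusted p = 5.28e-04, adjusted p = 0.309 with an estimated correlation). Slc1a5 fell from 106 ± 8 to 71.1 ± 6.7 CPM and Sesn2 from 110 ± 4 to 73.8 ± 9.2 CPM. Cholesterol synthesis genes fell for 6 of 23 and rose for 0 (7 and 0 adjusted over the list alone, camera adjusted p = 0.0102, adjusted p = 0.168 with an estimated correlation). Sqle went from 123 ± 8 to 92.5 ± 4.1 CPM.

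Glucose and incretin sensing genes of islets, the list that holds Tmem27, Kcnk16 and Gpr119, fell for 5 of 15 and rose for 1, also adjusted over the list alone (camera adjusted p = 0.00113, adjusted p = 0.124 with an estimated correlation). Glycolysis genes were not called as a list (5 of 23 higher, 1 lower, 6 and 2 adjusted over the list alone, camera adjusted p = 0.364), though Ldha, lactate dehydrogenase A, rose from 395 ± 31 to 607 ± 97 CPM and Hk2 from 0.451 ± 0.144 to 1.89 ± 0.26 CPM. Of the secretory granule genes, Scg2 fell from 3403 ± 127 to 2404 ± 100 CPM and Pam, which amidates peptide hormones, from 973 ± 33 to 645 ± 28 CPM. That list was not called (5 of 31 higher, 5 lower, 6 and 6 adjusted over the list alone, camera adjusted p = 0.302).

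Cdkn2a, a Polycomb target that encodes cell cycle inhibitors, was at 196 ± 21 CPM in DMSO and 220 ± 44 CPM with EPZ011989 (adjusted p = 0.415, edgeR), and passed without EPZ011989 replicate 2 (log2 fold change 0.28, adjusted p = 0.0419). Cdkn1a, the inhibitor p21, rose from 55.3 ± 3.2 to 91.1 ± 13.0 CPM, and Ccnd1, cyclin D1, from 2.87 ± 0.42 to 9.33 ± 0.63 CPM. Neither the CDK inhibitor list (3 of 7 higher, 0 lower, also adjusted over the list alone, camera adjusted p = 0.159, and 0.0493 without EPZ011989 libraries 2 and 4) nor the proliferation list (5 of 43 higher, 1 lower, 5 and 0 adjusted over the list alone, camera adjusted p = 0.328) was called.

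**Figure D3:**
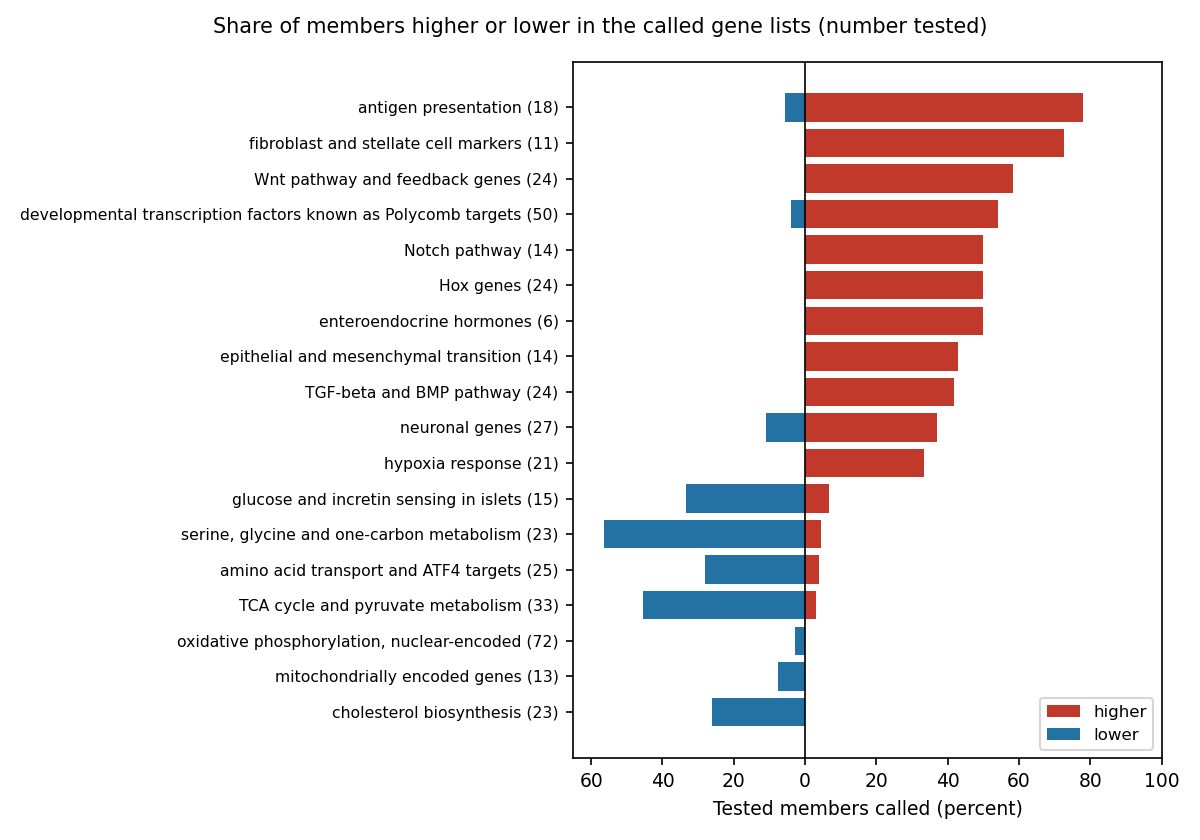
Bars give the percent of each list's tested members called higher (red, to the right) or lower (blue, to the left) with EPZ011989, for the 11 lists called higher and the 7 called lower by camera, with the number tested in parentheses. Antigen presentation reaches 14 of 18 members higher, and serine, glycine and one-carbon metabolism 13 of 23 lower.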

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

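The tests of a floor under low genes, of fibroblast transcripts and of Ins1 below were chosen after the results were seen. Among 268 groups of 4 or 5 values tested for a sample far from the others, 14 were found, where chance gives about 13.4. Groups with a count in a single library are always flagged, so that chance figure does not hold for them. With EPZ011989, Il1r2 was 5.78 CPM in library 4 against 4.05 to 4.27 in the others, and Cela1 was 7.80 CPM in library 4 against 5.78 to 6.11. Neurog3 had 0.0844 CPM in EPZ011989 library 2 and Pax4 0.119 CPM in EPZ011989 library 3, both against 0 in the other 3. In DMSO, Ldha was 340 CPM in library 1 (others 400 to 416), Slc1a5 120.0 CPM in library 5 (101.3 to 106.0), Syn2 6.28 CPM in library 3 (7.659 to 8.001) and Ccnd1 3.60 CPM in library 4 (2.56 to 2.82). Hoxc9 was 0.229 CPM in DMSO library 5 (0.0737 to 0.0947) and Psmb9 0.958 CPM in DMSO library 2 (1.56 to 1.80). Single DMSO libraries alone had counts of Cck (0.192 CPM, library 2), Anxa1 (0.0571 CPM, library 5), Col6a3 (0.0677 CPM, library 1) and Xaf1 (0.0589 CPM, library 2).

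Rises of at least 2-fold outnumbered falls by 29.8 to 1. Library scaling was argued against, since the lowest ratio over TMM, RLE, upper-quartile and library-size scaling was 26.9. How much of the imbalance comes from a floor that hides falls of low genes was left open. Of the rises 1220 were of genes under 10 CPM in DMSO, where falls are harder to see. Among genes with a DMSO mean of at least 10 CPM 62 rose and 8 fell, a ratio of 7.75 (95% Clopper-Pearson interval 3.70 to 18.7). Genomic DNA or background reads in the EPZ011989 libraries were left open. The summed level of 1445 olfactory, vomeronasal and taste receptor genes was 7.26 ± 0.64 CPM in DMSO and 8.32 ± 1.93 CPM with EPZ011989 (ratio 1.15, overlapping). In each library only 20 to 40 of these genes had a count, so few genes set the sum and it cannot decide this. Tested genes under 1 CPM rose 1.74-fold in sum. Genes without a count in DMSO pass the filter only through the EPZ011989 libraries, which can raise that ratio. Loss of repression under EZH2 inhibition remains a hypothesis, since histone methylation was not measured here.

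Fibroblast markers rose, and fibroblasts in the treated cultures would bring their most abundant transcripts along. Col1a1, Col1a2, Col3a1 and Sparc, named after their values were seen, together rose by 1.97 ± 0.24 CPM (SE), against 20.3 ± 3.0 CPM for Pdgfra alone, so fibroblasts were argued against. Of the 11 markers tested, 3 were at 1 CPM or more in DMSO cells and 2 stood in another list.

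Hormone genes such as Ins2 and Sst rose. Beta cells or their RNA would bring Ins1 along with Ins2, but Ins1 had a summed count of 0 in the EPZ011989 libraries against 1422 for Ins2, which argues against them. Whether few cells expressed much Ins2 or many expressed little was not tested.

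The real grouping gave 3562 called genes and 1325 changed at least 2-fold. It was the only 1 of 100 splits of the 9 libraries with so many of either, which argues against a random split. The highest other splits gave 856 and 615. A share of 1 in 100 is the smallest that these splits can give. They cannot tell the treatment from a culture or day shared within a group. For the 18 called lists chance cannot be excluded by this count, because 5 of 100 splits, the real one included, gave at least as many and the highest other gave 20. Of the 4 others, 2 kept all 4 EPZ011989 libraries together and 2 kept 3 of them together, while the 47 splits with 2 on each side gave at most 8. Those 47 called at most 1 gene each, so camera at the preset correlation can call lists where hardly any gene differs.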

How the results depend on the processing

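No called gene changed sign under any alternative given here, but calls were lost. The replicate block kept 57.0% of the 3562 calls, glmTreat 31.1% and the fits without 1 library 75.1% to 96.2%. Among 172 genes followed by name, the block lost the calls of 31, glmTreat of 75 and the other alternatives of at most 10 each. Of those in this text the block lost Mafa (0.0554), Jarid2 (0.0760), Rbbp7 (0.107), Isl1 (0.0727), Xaf1 (0.0784) and mt-Nd1 (0.170), and upper-quartile factors Rbbp7 (0.0575) and mt-Nd1 (0.0856). Falls of metabolic genes given by name, and rises such as Wnt4 and Ldha, were lost under glmTreat. Counts of genes higher (2388), lower (1174), higher by at least 2-fold (1282) and lower by at least 2-fold (43) stayed within 1.5 times except as follows. Upper-quartile factors gave 776 lower genes, the filter of at least 1 CPM in 4 libraries 824 higher by at least 2-fold (fewer low genes tested), and DESeq2 68 lower by at least 2-fold. Against a fold of 1.5, glmTreat, a stricter null, called 1075 higher and 31 lower, 24 of them by at least 2-fold. Leaving out single libraries gave 781 (without EPZ011989 replicate 3) to 2377 (without EPZ011989 replicate 2) lower genes and 34 to 103 lower by at least 2-fold. The cause was not tested. The replicate block on the 8 libraries numbered 1 to 4 left 1525 higher and 527 lower. Same-numbered libraries deviated from their group means at r = 0.01, -0.10, -0.04 and 0.03, so no pairing by number was seen. Other pairs reached r = -0.23 and 0.21. Length trends of single libraries enter these deviations too, so a culture or day shared by number cannot be excluded. Fewer libraries and degrees of freedom also enter the block fit. Of the alternatives chosen after seeing the data, counts divided by 4 gave 2099 higher and 1242 lower, removal of the length trend 2673 and 1628, and leaving out EPZ011989 libraries 2 and 4 2497 and 1752. The length correction was centred per library and fitted on genes of at least 5 CPM after a first version, uncentred and fitted on all genes, had shifted all fold changes and turned the sign of some calls. The values of that version are not reported.

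Of the 11 lists called higher and 7 lower by camera, 5 and 1 held with an estimated correlation. Those higher were antigen presentation, fibroblast markers, Hox genes, Wnt pathway and developmental transcription factors, and the one lower was serine, glycine and one-carbon metabolism. The tricarboxylic acid cycle (0.206), ATF4 target (0.309) and glucose and incretin sensing lists (0.124) did not. Fry, which does not compare a list with other genes, called 26 higher and 6 lower, the alpha identity list among the higher (adjusted p = 0.0280, the direction opposite to camera's). The beta identity list passed under no filter (0.00447), the replicate block (0.0320), counts divided by 4 (0.0223), fry (2.4e-06) and 6 of the 9 fits that left out 1 library (0.0180 to 0.0455), and not in the other 3 (up to 0.213, without EPZ011989 replicate 2). The median or mean differed in sign from camera for 7 lists, 0 of them called. Depth limits what can be said of genes under about 1 CPM.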

Other observations

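Several groups not described above moved as well. The epithelial and mesenchymal transition list rose (6 of 14 higher, 0 lower, 7 and 0 adjusted over the list alone, camera adjusted p = 0.0173, adjusted p = 0.260 with an estimated correlation), a call lost without EPZ011989 replicate 2 (0.126) and without libraries 2 and 4 (0.0521). Hypoxia response genes rose (7 of 21 higher, 0 lower, 8 and 0 adjusted over the list alone, camera adjusted p = 0.0308, adjusted p = 0.260 with an estimated correlation), a call lost without DMSO replicate 1 (0.0538) or 4 (0.0576) or EPZ011989 replicate 2 (0.0627), or without libraries 2 and 4 (0.0827). Egln3, an oxygen-sensing prolyl hydroxylase, went from 0.936 ± 0.327 to 5.44 ± 0.71 CPM. Mitochondrially encoded genes were lower as a list (1 of 13 lower, mt-Nd1, 0 adjusted over the list alone, camera adjusted p = 0.0259, adjusted p = 0.530 with an estimated correlation), a call lost with the 1 CPM filter (0.0512), the replicate block (0.0705), the length trend removed (0.0683) and fry (0.0792), and without DMSO replicate 5 (0.0596). The call of mt-Nd1 (0.0320) was itself lost without DMSO replicate 2 (0.0502), 4 (0.0697) or 5 (0.0532) or EPZ011989 replicate 3 (0.0993) or 4 (0.0527), and with upper-quartile factors (0.0856), the replicate block (0.170), the length trend removed (0.0637) and libraries 2 and 4 left out (0.0568). For nuclear-encoded oxidative phosphorylation genes camera ranked the list lower, though only 2 of 72 members fell and 0 rose (1 and 0 adjusted over the list alone, camera adjusted p = 0.0462, adjusted p = 0.785 with an estimated correlation). That call was lost with upper-quartile factors (0.0539), the 1 CPM filter (0.125), the replicate block (0.137), counts divided by 4 (0.0752) and fry (0.721), and without libraries 2 and 4 of EPZ011989 (0.0685). It was also lost without DMSO replicate 2 (0.103), 4 (0.0635) or 5 (0.138) or EPZ011989 replicate 1 (0.105) or 2 (0.808). The median log2 fold change of this list was -0.024, against -0.080 for all tested genes at 100 CPM or more. Lists that were not called included H3K27 demethylases and PRC1 subunits (5 of 21 higher, 1 lower, adjusted p = 0.817), ribosomal proteins (adjusted p = 0.276, and 0.00912 without EPZ011989 replicate 4), fatty acid oxidation (5 of 28 higher, 5 lower, adjusted p = 0.488), genes of the unfolded protein response (2 of 27 higher, 1 lower, adjusted p = 0.483), imprinted genes (6 of 22 higher, 1 lower, adjusted p = 0.108, and 0.0259 and 0.0410 without EPZ011989 replicate 3 or 4), genes disallowed in beta cells (5 of 13 higher, 2 lower, adjusted p = 0.503), acinar markers (1 of 3 higher, 1 lower, adjusted p = 0.817), germline genes (2 of 7 higher, 0 lower, adjusted p = 0.349), fatty acid synthesis and lipid storage (6 of 25 higher, 2 lower, adjusted p = 0.494), apoptosis and p53 targets (4 of 20 higher, 5 lower, adjusted p = 0.160) and immediate early and heat shock genes (6 of 16 higher, 1 lower, adjusted p = 0.488). Adjusted over the list alone, their counts in the order given, without ribosomal proteins, were 5 and 1, 5 and 5, 2 and 0, 7 and 1, 5 and 2, 1 and 1, 2 and 0, 7 and 3, 4 and 5, and 8 and 1.

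Counts of 0 in all 5 DMSO libraries and at least 1 count in each of the 4 EPZ011989 libraries were found for 241 genes, and the converse for 4. Of the 241, 109 passed the filter and all 109 were called. Genes with a count numbered 15777 to 16346 per DMSO library and 17285 to 17924 per EPZ011989 library.

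A hypothesis is that the 2-fold rises mark genes silenced over CpG-rich starts and in domains, as Polycomb targets often are. The median ratio of observed to expected CpG in the first 500 nt of the longest annotated transcript was 0.595 for 1229 risen protein-coding genes, above all of 10000 random lists matched on mean level (percentile 100, median 0.516). Among genes with a mean of at least 10 CPM a trend with transcript GC was too small to give 2-fold rises, since median log2 fold changes of the highest and lowest decile by GC differed by 0.10. Among genes under 10 CPM, where most rises lay, they differed by 0.45 ± 0.05 (bootstrap SE), so a share of a GC trend in those rises was left open. Of 1233 risen protein-coding genes 384 had a risen next neighbour, again above all random lists (percentile 100, mean 237). Both are consistent with the hypothesis, but gene families that share reads or regulators lie in runs too, and lists were matched on level alone.

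The longest runs of tested protein-coding genes that all rose at least 2-fold, named after their values were seen, held 10 genes of the MHC region from H2-DMa to Notch4 (chromosome 17, 34119541 to 34588503, GRCm38) and 7 genes from Hoxc13 to Hoxc4 (chromosome 15, 102921103 to 103036852). Another held 7 protocadherin genes from Pcdha2 to Pcdhb7 (chromosome 18, 37005203 to 37345202), near-identical copies whose reads can be shared.

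Libraries differed within groups in a trend with transcript length. Across 10253 genes, Spearman's rho between exon length and deviation from the group mean ran from -0.58 to 0.57 in DMSO and from -0.61 to 0.57 with EPZ011989, with libraries 2 and 4 of EPZ011989 at 0.57 and -0.61. The group difference itself had rho = -0.02. Genes are not independent replicates.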
